A study of Homo sapiens with 107 samples.

How the data were processed

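The samples were RNA libraries of PTEC-TERT1 cells treated with 1 of 5 ASOs or with vehicle, with or without exogenous EGF, and harvested 6 h after ASO addition, per the labels' protocols. From each culture 10 ng of total RNA was reverse transcribed and amplified with the Ion AmpliSeq RNA library kit, per the labels' protocols. The growth medium of the line contained 10 ng/ml EGF, and what the medium of the columns labelled without EGF contained is not given in the sources used here. The deposited values were whole-number counts per gene of a targeted panel of 1035 genes in 107 columns, not normalised by the authors as far as the values show, and each gene came with its symbol and RefSeq transcript. The genome build was hg19, per the submitters' processing notes. The aligner, the counter and any filter are not given in the sources used here. All 107 columns were matched to samples by their titles, and 0 columns belonged to no sample.

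Columns were compared value for value before any test. Those with identical counts in every gene were treated as 1 library, which left 57 libraries, and the 2 most similar distinct libraries differed in 912 of 1035 genes. Within the columns of 1 dose label no library occurred more than once, so n counts columns there. The labels call the replicates biological without stating that they came from separate cultures, so p-values measure the spread between these columns, which may be partly technical. Total counts ran from 1658672 to 8167098 per library, with a median of 3264265, and 9 to 158 genes stood at 0 in a library, with a median of 64. Reads of an amplicon panel carry no molecular identifiers here, so counts are not independent molecules.

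Tests were made on the deposited counts with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood F-test, low-count filter by filterByExpr, TMM scaling, Benjamini-Hochberg adjustment over the genes tested, adjusted p under 0.05). Before the data were examined, the groups, the planned fit, its alternatives, the gene lists and the rule for naming genes were fixed. The planned fit had 36 group means over all 107 columns, with contrasts for EGF in vehicle cultures, each ASO against the vehicle of the same dose label, the interaction with EGF and each ASO against Scramble-A at 100 µM, and 100 against 10 µM. Because that fit counts a repeated library several times and places some libraries in both arms of a comparison, 2 further analyses were added after the data had been seen. The first used each library once where all its columns carried 1 label. The second, added after the results of the others were known, fitted each dose label alone with terms for EGF and compound, and with their interaction in a separate fit. Fold changes are log2 with their SE, levels are log2 CPM with a prior count of 2, and intervals are 95% intervals.

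The rule for naming genes took, for EGF and for each ASO against vehicle, the 10 highest and 10 lowest log2 fold changes among genes past the threshold, with a mean log2 CPM of at least 3 and the same sign in each stratum. The strata were the 3 dose labels for EGF and both EGF states for an ASO. For interactions and for comparisons with Scramble-A it took the 5 smallest adjusted p past the threshold. From each list it took up to 4 members with the smallest p, and it always took MYD88, EGF and EGFR. PCSK9, HAVCR1, LCN2 and CLU belonged to the rule but had no row on the panel. The rule was written for 100 µM and for EGF in vehicle, and was carried over to each dose label. Genes named from the analysis of libraries with 1 label, and those of the dose contrast, were chosen after their values were seen.

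The 25 gene lists covered growth factor, inflammatory, interferon, stress, metal, lipid, lysosome, cell cycle, apoptosis, matrix, hypoxia, tubule, injury, glucocorticoid and Toll-like receptor genes and markers of other cell types. The 19 lists with at least 5 tested genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and with an estimated correlation, adjusted over the lists. The lists for LXR and lipid efflux, oxidative phosphorylation, proteasome, and endothelial, stromal and blood cells had 4, 3, 0, 4, 2 and 2 genes on the panel and were not tested, so contamination by other cell types was not examined.

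Alternatives were DESeq2 1.42.0 (Wald test, adjusted p under 0.05), its size factors in edgeR, no count filter, only the compared groups, vehicles pooled over dose labels, each EGF state alone, and leaving out each replicate. Added after seeing the data were covariates, libraries of 1 or several columns, removal of libraries with both EGF labels, vehicle cultures only, thinning to the lowest total, and removal of a transcript GC trend per library by loess with a span of 0.7. Transcript GC came from GENCODE 29, a GRCh38 annotation used for no coordinates, and was available for 1009 genes (97.5%). The scripts were tested on simulated counts with the real means, library sizes and spread before they were applied. In the simulated EGF comparisons 77%, 78.8% and 54% of genes changed 2-fold were recovered at 10, 30 and 100 µM labels, over 895, 897 and 903 genes, and in those of Myd88-E against vehicle 31.3%, 19.2% and 21%. These simulations took every deposited label as right. Permutation tests and plots used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and thinning was done in R. Other splits of the columns were refitted for comparisons with at least 3 columns or libraries per arm, 100 times each within dose labels and for single-label libraries, and 40 times in the planned fit.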

Results

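RNA levels of 1035 genes were read by amplicon sequencing in PTEC-TERT1 cells, a human kidney proximal tubule epithelial line immortalised with telomerase. Cells were harvested 6 h after addition of an antisense oligonucleotide (ASO) or of the saline vehicle, with or without exogenous epidermal growth factor (EGF), to assess ASO toxicity. The 5 ASOs were Scramble-A, named as a scrambled sequence, PCSK9-B, PCSK9-C and PCSK9-D, named after a secreted regulator of the LDL receptor, and Myd88-E, named after the adaptor of Toll-like and interleukin-1 receptors. The labels gave 3 biological replicates per condition and concentrations of 10, 30 and 100 µM, which the vehicle columns also carried. The 107 deposited columns fell into 36 groups of 2 to 4 columns, with 37 columns labelled 10 µM, 37 labelled 30 µM and 33 labelled 100 µM, and 19 of them were vehicle. Total counts ran from 1658672 to 8167098 per distinct column, with a median of 3264265. SPP1, which encodes the matrix protein osteopontin, took a median of 7.89% of the counts, ANXA2, a membrane-binding annexin, 5.93%, and PLAU, the urokinase protease, 3.03%.

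Only 57 of the 107 columns held distinct counts, and 50 repeated an earlier column value for value under another label. A distinct column is called a library here: 21 libraries stood in 1 column, 22 in 2 columns and 14 in 3 columns. Of the 36 libraries in several columns, all 36 carried conflicting dose labels, 33 conflicting compound labels and 11 conflicting EGF labels, and 12 were labelled both vehicle and ASO. No library appeared more than once within 1 dose label (0 repeats), so each comparison below was made inside the columns of 1 dose label, an approach adopted after the repeats and the results of the planned fit had been seen. The fit planned before the data were examined used all 107 columns as separate samples, and its counts are given beside each comparison. Because most libraries carried several dose labels (29 of 37 columns at 10 µM, 29 of 37 at 30 µM and 28 of 33 at 100 µM), the 3 labels give neither independent repeats nor a concentration series. All conditions named below are those of the column labels.

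**Figure D1:**
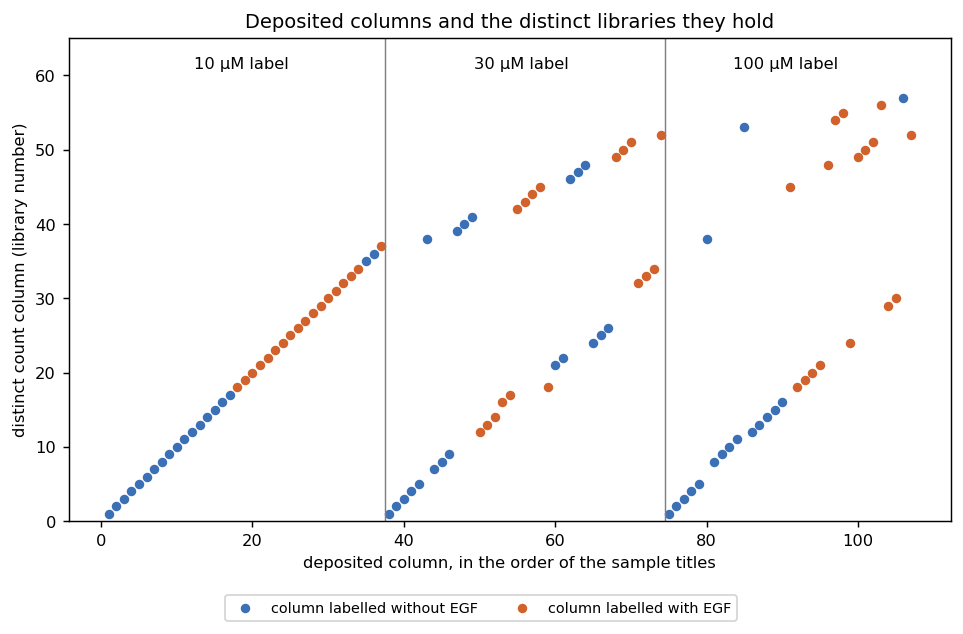
Library number (vertical axis) of each of the 107 deposited columns in title order (horizontal axis), coloured by EGF label, with the 10, 30 and 100 µM labels as blocks. The 57 libraries recur across the dose labels, and none recurs within 1 dose label.

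The named targets were examined first. PCSK9 had no row on the panel, so the PCSK9 ASOs could not be checked against their target, whereas MYD88 (NM_002468) was measured. In the columns labelled 10 µM, MYD88 fell by 1.17 on the log2 scale with Myd88-E against vehicle (SE 0.39, 95% interval -1.95 to -0.40, edgeR adjusted p = 0.0418), from 8.11 ± 0.57 log2 CPM (SD, n = 6) to 6.74 ± 0.98 (SD, n = 6). All 6 of 6 Myd88-E columns lay below the vehicle median. With 30 µM labels the difference was -0.15 (SE 0.49, 95% interval -1.12 to 0.81, edgeR adjusted p = 0.842), with 7.43 ± 0.45 log2 CPM (SD, n = 7) in vehicle and 7.07 ± 1.00 (SD, n = 6) in Myd88-E. Columns labelled 100 µM gave 0.88 (SE 0.58, 95% interval -0.26 to 2.03, edgeR adjusted p = 0.415), with 6.19 ± 1.43 log2 CPM (SD, n = 6) in vehicle and 7.28 ± 1.06 (SD, n = 6) in Myd88-E, 1 of whose columns stood apart at 5.19. The library at 5.19 was labelled Myd88-E wherever it stood, as was a library at 7.65. The other Myd88-E libraries at this label also carried other compound labels. MYD88 was thus not detectably lower in the columns labelled Myd88-E at 30 and 100 µM. At each dose label the vehicle arm held a library that was labelled Myd88-E under another dose label. Vehicle was therefore not a clean reference, and these differences do not settle whether Myd88-E lowers its target. The call at 10 µM ended with DESeq2 size factors (adjusted p = 0.0544 in edgeR), without the filter on low counts (0.0722) and with only the compared groups in the fit (0.222). In the planned fit of all columns the MYD88 differences were -1.17, -0.18 and 0.79 at 10, 30 and 100 µM (edgeR adjusted p = 0.142, 0.798 and 0.357). Among libraries with 1 compound label the difference was -0.75 (SE 0.78, edgeR adjusted p = 0.593), from 7.21 ± 1.39 log2 CPM (SD, n = 5) in vehicle to 6.57 ± 1.11 (SD, n = 5) in Myd88-E, and PCSK9-B gave -1.01 (SE 0.78, edgeR adjusted p = 0.936). The other 4 ASOs at 10 µM labels gave MYD88 differences from -0.75 (PCSK9-C) to -0.39 (PCSK9-D), none past the threshold, and Myd88-E against Scramble-A gave -0.71 (SE 0.38, edgeR adjusted p = 0.898).

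**Figure D2:**
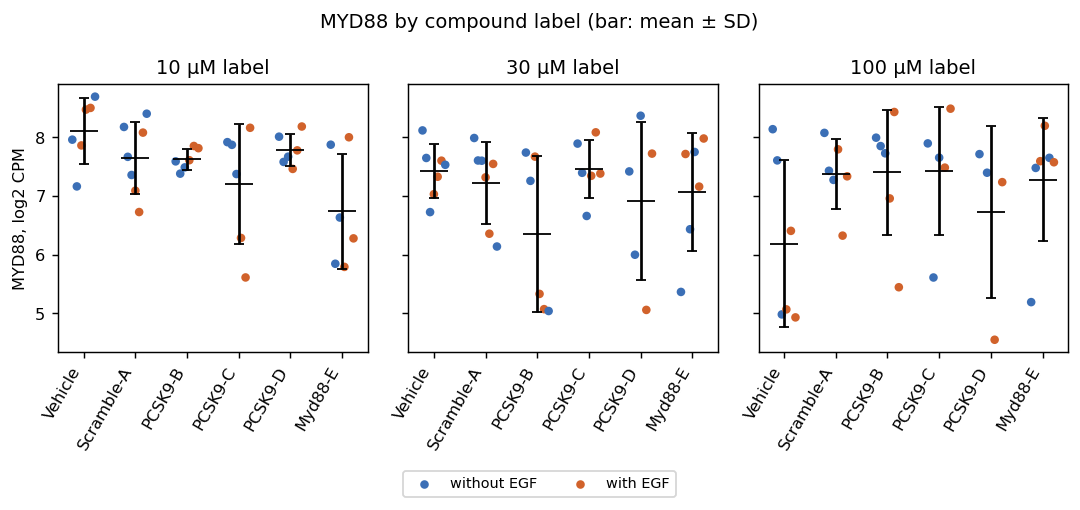
MYD88 level (log2 CPM, vertical axis) in each column by compound label (horizontal axis), 1 panel per dose label, coloured by EGF label, with bars for the mean ± SD. Myd88-E columns averaged 6.74 against 8.11 in vehicle at 10 µM labels, and 7.28 against 6.19 at 100 µM labels.

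The effect of exogenous EGF was asked next. In the columns labelled 10 µM, 16 of 20 measured genes of the EGF and ERK response list rose with EGF. DUSP6 (NM_001946), a phosphatase that inactivates ERK, rose by 2.50 on the log2 scale (SE 0.28, edgeR adjusted p = 4.36e-09), from 7.01 ± 0.88 log2 CPM (SD, n = 19) without EGF to 9.51 ± 0.88 (SD, n = 18) with it, and lay above the no-EGF median in 18 of 18 columns. EGR1, an immediate-early transcription factor, rose by 2.51 (SE 0.38, edgeR adjusted p = 2.47e-06; 17 of 18 columns), from 2.18 ± 1.23 to 4.73 ± 1.06 log2 CPM. ETV5 rose by 2.28 (SE 0.26) and ETV4 by 1.73 (SE 0.29), both ETS-family transcription factors, and FOS, an AP-1 subunit, rose by 2.19 (SE 0.32). AREG, a ligand of the EGF receptor, rose by 1.93 (SE 0.31; 18 of 18 columns), and SERPINE1, the plasminogen activator inhibitor, by 2.03 (SE 0.27; 18 of 18 columns). TNFRSF6B, PTGS1, VDR, F3, DUSP1 and FURIN rose by 1.39, 1.24, 1.22, 1.16, 1.15 and 1.13. FGFR2 (NM_022970), a fibroblast growth factor receptor, fell by 1.86 (SE 0.18, edgeR adjusted p = 2.98e-10; 18 of 18 columns below the no-EGF median), from 8.88 ± 0.45 to 6.97 ± 0.61 log2 CPM. ESRRG, an orphan nuclear receptor, fell by 2.00 (SE 0.33), EFNA1, an ephrin ligand, by 1.68 (SE 0.24), IFIT2, an interferon-induced gene, by 1.67 (SE 0.22), and SLC15A2, a peptide transporter of the tubule, by 1.32 (SE 0.22). TNFRSF1A, RCAN1, MAT2A, VCAN and MMP14 fell by 1.5, 1.21, 1.07, 1.04 and 1.00.

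Of the 895 genes tested at 10 µM labels, 322 changed with EGF, 161 up and 161 down (edgeR, adjusted p under 0.05). In the vehicle columns alone only 4 genes passed, with VDR at -0.19, and 186 passed without the libraries that carried both EGF labels, 10 of the 37. The planned fit called 0 of 951 genes for EGF in vehicle cultures with edgeR (62 at an unadjusted p under 0.05; 0 with DESeq2), in a comparison where 1 library stood in both arms.

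In the columns labelled 100 µM, 6 of 20 measured genes of the EGF and ERK response list and 13 of 20 measured cell cycle genes rose with EGF. DUSP6 rose by 1.88 (SE 0.41, edgeR adjusted p = 0.00128; 15 of 16 columns), from 7.02 ± 1.5 log2 CPM (SD, n = 17) to 9.16 ± 1.34 (SD, n = 16). ETV5 rose by 1.75 (SE 0.36), FOS by 2.12 (SE 0.43) and EGR1 by 1.46 (SE 0.50). ACLY (NM_001096), which makes cytosolic acetyl-CoA, rose by 0.94 (SE 0.16, edgeR adjusted p = 0.000133; 16 of 16 columns), from 11.05 ± 0.32 to 12.01 ± 0.45 log2 CPM. HMGCS1, an enzyme of the mevalonate pathway, rose by 0.95 (SE 0.18; 16 of 16 columns), and FAS, a death receptor, by 1.09 (SE 0.24; 14 of 16 columns). CCNE1, XIAP, SYK, PKP2, TNFRSF10A and CLOCK rose by 0.87, 0.85, 0.84, 0.83, 0.83 and 0.83. ESRRG fell by 1.90 (SE 0.41; 15 of 16 columns), SLCO3A1, an organic anion transporter, by 1.85 (SE 0.34; 15 of 16 columns), PINK1, a mitochondrial kinase of mitophagy, by 1.69 (SE 0.32), and PNPLA2, a triglyceride lipase, by 1.68 (SE 0.31). PTH1R, CXCL16, MMP14, AXL and EMX2 fell by 1.55, 1.5, 1.40, 1.31 and 1.30. Of the 903 genes tested 271 changed, 99 up and 172 down (edgeR, adjusted p under 0.05). The vehicle columns alone gave 0 calls with edgeR at 100 µM labels, with EMX2 at 0.90, and 95 genes passed without the libraries carrying both EGF labels, 7 of the 33.

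No gene passed for EGF at 30 µM labels. The differences of the plotted genes were EGR1 0.19 (SE 0.46), DUSP6 -0.11 (SE 0.44), ETV5 -0.11 (SE 0.38), AREG 0.12 (SE 0.36), ESRRG -0.25 (SE 0.42) and FGFR2 -0.21 (SE 0.31), with 20 columns without and 17 with EGF. EdgeR called 0 of 897 genes, with 50 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0698, and DESeq2 called 1. In simulated data with these columns' spread, 78.8% of genes changed 2-fold were recovered at this label, over 897 genes. That simulation took every EGF label as right, so it does not measure how wrong labels would hide a response. The difference in EGF response between dose labels was not tested, because 22 libraries stood under both 10 and 30 µM labels and 21 under both 10 and 100 µM labels. Of 892 genes tested at both 10 and 100 µM labels, 66 rose in both, against 17.9 for independent lists, and 58 fell in both, against 31.0. The 21 libraries under both labels entered both lists.

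**Figure D3:**
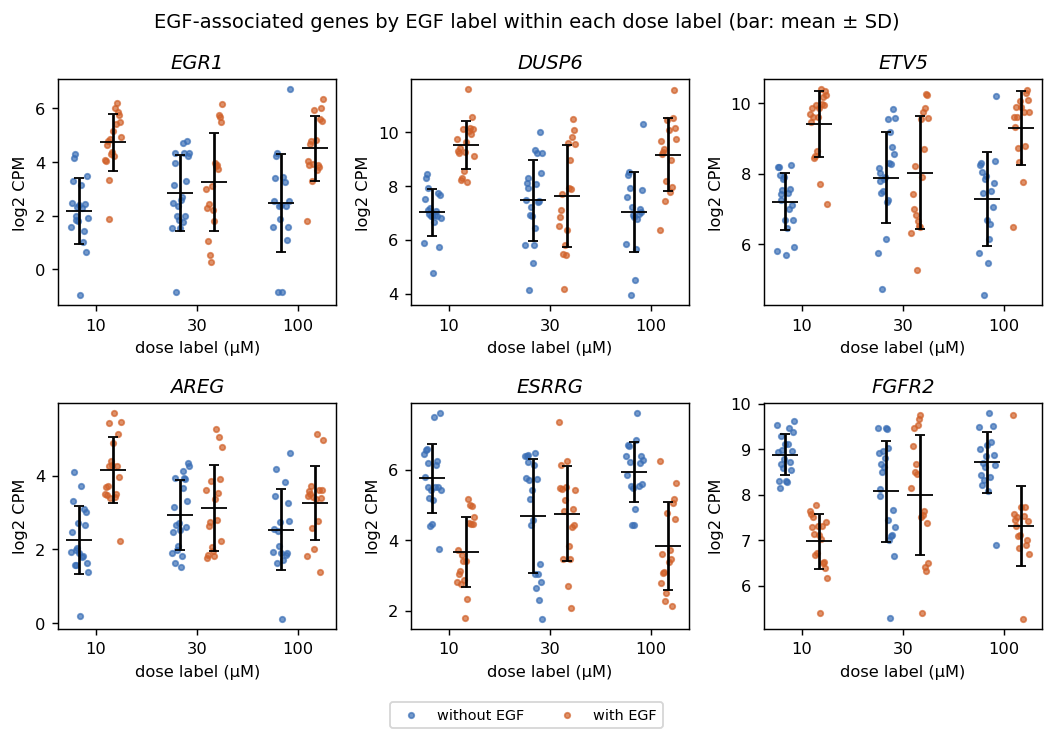
Levels (log2 CPM, vertical axes) of EGR1, DUSP6, ETV5, AREG, ESRRG and FGFR2 in each column, by dose label and EGF label (horizontal axis), with bars for the mean ± SD. At 10 µM labels DUSP6 averaged 7.01 without and 9.51 with EGF, and FGFR2 averaged 8.88 and 6.97.

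Gene lists fixed before the data were examined were described by the same EGF comparisons. Of 20 measured genes of the EGF and ERK response list, 16 rose and 0 fell at 10 µM labels (16 adjusted over the list alone), with a median log2 change of 1.15. The limma camera test gave adjusted p = 1.20e-07 at its preset correlation, and adjusted p = 0.261 with an estimated correlation. In the 100 µM columns 6 of 20 rose and 0 fell (6 adjusted over the list alone), with a median of 0.41 and a camera adjusted p = 0.000575, and adjusted p = 0.822 with an estimated correlation. In the 30 µM columns 0 of 20 passed with edgeR, and the camera adjusted p was 0.234. In the planned fit of EGF in vehicle cultures this list had a median of 0.49 and the cell cycle list one of 0.60, with 0 of 20 members past the test in each by edgeR, also adjusted over the list alone (camera adjusted p = 2.06e-05 and 0.000100, and adjusted p = 0.557 for both with an estimated correlation). No list call of any comparison held with an estimated correlation.

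Cell cycle and proliferation genes were counted under both labels, and the difference between the labels was not tested. In the 100 µM columns 13 of 20 rose and 0 fell (17 adjusted over the list alone), with a median of 0.95; camera gave adjusted p = 4.68e-06, and adjusted p = 0.668 with an estimated correlation. CCNA2, cyclin A2, rose by 1.84 (SE 0.48; 11 of 16 columns), CDC6, a replication licensing factor, by 1.40 (SE 0.35), PCNA, the polymerase clamp, by 1.30 (SE 0.31) and CCNB1, cyclin B1, by 1.18 (SE 0.31). At 10 µM labels 1 of 20 rose and 6 fell (1 and 6 adjusted over the list alone; camera adjusted p = 0.666), among them CCNA2, which fell by 0.69 (SE 0.17; 16 of 18 columns). In the EGF receptor family and its ligands, 5 of 10 rose and 3 fell at 10 µM labels (the same counts adjusted over the list alone; camera adjusted p = 0.648). HBEGF, a heparin-binding ligand, rose by 1.00 (SE 0.23), EGF itself fell by 0.84 (SE 0.20) and ERBB3 fell by 0.96, whereas EGFR differed by 0.28 (SE 0.16, edgeR adjusted p = 0.158). At 100 µM labels EGF differed by 0.01 (SE 0.22, edgeR adjusted p = 0.989) and EGFR by 0.31 (SE 0.19, edgeR adjusted p = 0.225). Of 7 sterol and lipid synthesis genes 4 rose at 10 µM labels and 2 at 100 µM labels, and 0 fell (camera adjusted p = 0.648 and 0.104; 4 and 2 adjusted over the list alone).

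Of 19 interferon-response genes, 7 fell with EGF at 10 µM labels, 0 rose and 12 did not pass (7 and 1 adjusted over the list alone; camera adjusted p = 0.312). IFIT3, STAT2 and MX1 fell by 0.96, 1.14 and 0.88. In the NF-kB and inflammation list 7 of 22 rose and 3 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.649). IL8, the neutrophil chemokine, rose by 1.93 (SE 0.21; 17 of 18 columns) and SOD2, the mitochondrial superoxide dismutase, fell by 0.84. IL8 also rose at 100 µM labels, by 1.68 (SE 0.28; 15 of 16 columns). HMOX1, haem oxygenase 1, fell by 1.52 (SE 0.33) at 10 µM labels and by 1.92 (SE 0.44) at 100 µM labels, where CAT, catalase, fell by 1.72 (SE 0.39) and 4 of 11 genes of the NRF2 and oxidative stress list fell with 0 rising (4 adjusted over the list alone; camera adjusted p = 0.673).

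The response to each ASO against vehicle was compared within each dose label. With Myd88-E at 10 µM labels, VCAM1, a leukocyte adhesion molecule, rose by 1.96 (SE 0.41, edgeR adjusted p = 0.0189), from 2.23 ± 0.29 log2 CPM (SD, n = 6) to 3.95 ± 0.76 (SD, n = 6), and was above the vehicle median in 6 of 6 columns. IFI16, a DNA sensor, rose by 1.70 (SE 0.54), MT1E, a metallothionein, by 1.61 (SE 0.54), LOX, a collagen cross-linking oxidase, by 1.54 (SE 0.43), and CD44, the hyaluronan receptor, by 1.5 (SE 0.46; 5 of 6 columns). HEXA, GCLC, PIK3R1, DDX58 and NRG1 rose by 1.53, 1.43, 1.35, 1.35 and 1.29. MCM2, a subunit of the replicative helicase, fell by 1.67 (SE 0.39, edgeR adjusted p = 0.0189; 6 of 6 columns), and SREBF2, the transcription factor of cholesterol synthesis, by 1.60 (SE 0.36, edgeR adjusted p = 0.0189; 6 of 6 columns), from 12.15 ± 0.53 to 10.42 ± 0.88 log2 CPM. FOXM1, a mitotic transcription factor, fell by 1.54 (SE 0.47), PLK1, a mitotic kinase, by 1.29 (SE 0.35), MX1 by 1.5 (SE 0.41) and STAT1, a mediator of interferon signalling, by 1.49 (SE 0.41). SOX6, ALDH7A1, COPS5, SOX4, GSTM3 and TASP1 fell by 1.67, 1.62, 1.60, 1.60, 1.60 and 1.60. In the cell cycle and proliferation list 4 of 20 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.833).

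Of 895 genes 117 changed with Myd88-E at 10 µM labels, 16 up and 101 down (edgeR), whereas DESeq2 size factors gave 151 in edgeR, 76 up and 75 down, and moved the median gene from -0.08 to 0.14. Leaving out 1 of the 12 columns moved the count by over 1.5 times in 11 fits, from 0 without vehicle without EGF replicate 3 to 294 without Myd88-E with EGF replicate 2, and with only the compared groups in the fit 0 genes passed with edgeR (346 at an unadjusted p under 0.05 in the fit of all columns of this label; DESeq2 called 272). With Myd88-E at 30 µM labels edgeR called 0 of 897 genes (240 at an unadjusted p under 0.05; 6 with DESeq2; 89 with only the compared groups), and at 100 µM labels 0 of 903 (178; 7 with DESeq2). The count at 100 µM labels was 124 without Myd88-E without EGF replicate 1 and 5 without vehicle without EGF replicate 2.

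PCSK9-C at 10 µM labels also came with higher VCAM1, by 1.70 (SE 0.41, edgeR adjusted p = 0.0218; 6 of 6 columns), from 2.23 ± 0.29 log2 CPM (SD, n = 6) to 3.76 ± 0.61 (SD, n = 6). CCL20, a chemokine of the NF-kB list, rose by 2.66 (SE 0.59; 6 of 6 columns). SLC15A2, the peptide transporter, fell by 2.05 (SE 0.39, edgeR adjusted p = 0.00559; 6 of 6 columns), from 4.55 ± 0.88 to 2.58 ± 1.06 log2 CPM. CDKN2C, a cyclin-dependent kinase inhibitor, fell by 1.55 (SE 0.39), CDH1, E-cadherin, by 1.28 (SE 0.34), and DDIT3, a stress-response transcription factor, by 1.18 (SE 0.33). SOX6, RND2, GSTM3, MAP2, TGFB3, NAA20, ACACB and GLA fell by 2.01, 1.70, 1.66, 1.46, 1.44, 1.39, 1.39 and 1.39. Of 895 genes 21 changed, 2 up and 19 down (edgeR; 18 with DESeq2 size factors, 4 up and 14 down; 69 with DESeq2). Leaving out 1 column took this count from 1 without PCSK9-C with EGF replicate 2 to 198 without vehicle without EGF replicate 2, and with only the compared groups it was 0 with edgeR (200 at an unadjusted p under 0.05 in the fit of all columns of this label). That vehicle library carried a Scramble-A label under another dose label.

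Metallothioneins, metal-binding stress proteins, had positive medians with each ASO at 10 µM labels, although 0 of 5 passed on their own for PCSK9-C with edgeR (3 adjusted over the list alone). For PCSK9-C the median was 1.26 with a camera adjusted p = 0.00216, and adjusted p = 0.543 with an estimated correlation. For PCSK9-B it was 1.12 with a camera adjusted p = 0.000218, and adjusted p = 0.176 with an estimated correlation. For PCSK9-D it was 0.75 with a camera adjusted p = 0.000489, and adjusted p = 0.334 with an estimated correlation. For Scramble-A it was 0.38 with a camera adjusted p = 0.0416, and adjusted p = 0.872 with an estimated correlation; DESeq2 size factors ended that call (0.0978). For Myd88-E it was 1.16 with a camera adjusted p of 0.232. These comparisons share the same vehicle columns. Cell cycle genes had a median of -0.66 with PCSK9-B (0 of 20 past the test over all genes with edgeR, 8 lower adjusted over the list alone), with a camera adjusted p = 0.000218, and adjusted p = 0.115 with an estimated correlation. With PCSK9-D the cell cycle median was -0.42 (0 of 20 past the test by edgeR, also adjusted over the list alone; camera adjusted p = 0.0256, and adjusted p = 0.334 with an estimated correlation).

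The EGF and ERK response list had positive medians with several ASOs under the other labels, although 0 of 20 members passed over all genes by edgeR in each case, and 0 adjusted over the list alone except where given. Under 30 µM labels its median was 0.60 with PCSK9-C (camera adjusted p = 2.02e-08, and adjusted p = 0.394 with an estimated correlation) and 0.97 with PCSK9-D (8.92e-05, and adjusted p = 0.633 with an estimated correlation). Under 100 µM labels it was 0.50, 0.58, 0.57 and 1.38 with Scramble-A, PCSK9-B, PCSK9-D and Myd88-E (camera adjusted p = 0.0329, 0.00927, 0.0129 and 0.000183, and adjusted p = 0.852, 0.668, 0.761 and 0.687 with an estimated correlation), where 9 members were higher with Myd88-E adjusted over the list alone. The cell cycle median was 0.81 with PCSK9-C and 1.12 with Myd88-E at 30 µM labels and -0.50 with PCSK9-C at 100 µM labels (camera adjusted p = 0.00211, 0.00661 and 0.0462, and adjusted p = 0.399, 0.796 and 0.744 with an estimated correlation), and 8 members were higher with Myd88-E at 30 µM adjusted over the list alone. DESeq2 size factors ended the call of PCSK9-C at 100 µM labels (camera adjusted p = 0.0510). At 30 µM labels the NF-kB and inflammation median was 0.31 with PCSK9-C and the kidney injury marker median -0.35 with PCSK9-B (0 members past the test by edgeR over all genes or adjusted over the list alone; camera adjusted p = 0.0200 and 0.0493, and adjusted p = 0.394 and 0.669 with an estimated correlation), and DESeq2 size factors ended the kidney injury call (0.0573). In the planned fit at 100 µM the EGF and ERK response list was higher by camera with each of the 5 ASOs (10 members with Myd88-E adjusted over the list alone, 0 with the others by edgeR), and with PCSK9-C the matrix list was higher and the cell cycle list lower, all lost with an estimated correlation (adjusted p from 0.482 to 0.873). FGFR2, which fell with EGF at 10 µM labels, differed between these arms. At 30 µM labels it was 7.44 to 9.54 log2 CPM in vehicle, 6.31 to 8.81 in PCSK9-C and 5.29 to 8.13 in PCSK9-D. At 100 µM labels vehicle with EGF replicate 1 stood at 9.76, against 5.27 to 7.73 in the other EGF columns. Myd88-E without EGF replicate 3 stood at 6.89, against 8.07 to 9.79 in its counterparts. The list medians cannot be told apart from an uneven EGF state.

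For the other ASOs no gene passed. At 10 µM labels edgeR called 0 of 895 genes for Scramble-A, PCSK9-B and PCSK9-D (156, 176 and 107 at an unadjusted p under 0.05), and DESeq2 called 0 for each. A single vehicle column decided these zeros: without vehicle without EGF replicate 2, edgeR called 4, 221 and 44. The library of that column was also labelled vehicle with EGF at 30 µM and Scramble-A without EGF at 100 µM. Under 30 µM labels edgeR called 0 of 897 genes for Scramble-A, PCSK9-B, PCSK9-C and PCSK9-D (5, 4, 21 and 103 at an unadjusted p under 0.05), and DESeq2 called 0 for each. Under 100 µM labels edgeR called 0 of 903 genes for the same 4 ASOs (40, 66, 58 and 41 at an unadjusted p under 0.05), and DESeq2 called 0 for each. In simulated data of the Myd88-E comparison at 100 µM labels, 21% of genes changed 2-fold and 74% of genes changed 4-fold were recovered, over 903 genes. Every label was taken as right there. The comparisons of the other ASOs were not simulated within dose labels. Between TMM scaling and DESeq2 size factors the median gene moved by 0.18, 0.14, 0.14, 0.17 and 0.22 for Scramble-A, PCSK9-B, PCSK9-C, PCSK9-D and Myd88-E against vehicle at 10 µM labels, and by -0.11, -0.15, -0.17 and -0.11 for Scramble-A, PCSK9-B, PCSK9-D and Myd88-E at 100 µM labels. The planned fit of all 107 columns called genes in 2 of its 15 ASO comparisons, 8 for PCSK9-D (4 up, 4 down) and 12 for Myd88-E (6 up, 6 down), both at 30 µM, and 0 of 951 in the others with edgeR (5 to 265 at an unadjusted p under 0.05; DESeq2 called 6 for PCSK9-C at 10 µM, 18 for Myd88-E at 10 µM, 3 for Myd88-E at 100 µM and 0 in the rest). For PCSK9-D and Myd88-E those counts became 5 and 0 without the filter on low counts, 22 and 128 with DESeq2, and 0 and 106 with only the compared groups, and leaving out 1 replicate gave 0 to 23 for PCSK9-D (0 without vehicle replicate 3, 23 without vehicle replicate 4) and 0 to 127 for Myd88-E (0 without vehicle replicate 1, 127 without vehicle replicate 3).

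Against the scrambled oligonucleotide, PCSK9-C stood apart in 2 genes at 10 µM labels. SLC15A2 fell by 2.12 (SE 0.39, edgeR adjusted p = 0.00233; 6 of 6 columns below the Scramble-A median), from 4.66 ± 0.90 log2 CPM (SD, n = 7) to 2.58 ± 1.06 (SD, n = 6). PCP4, a calmodulin-binding peptide, fell by 1.94 (SE 0.42, edgeR adjusted p = 0.0176; 6 of 6 columns), from 3.67 ± 0.99 to 1.94 ± 0.67 log2 CPM. DESeq2 called 3 genes in this comparison, and in each EGF state alone edgeR called 0. In 4 of the 13 fits that left out 1 column, only 1 gene passed by edgeR. For PCSK9-B, PCSK9-D and Myd88-E against Scramble-A at 10 µM labels edgeR called 0 of 895 genes (205, 37 and 23 at an unadjusted p under 0.05, and 44, 0 and 0 with DESeq2). Without Scramble-A without EGF replicate 3, edgeR called 41 for PCSK9-B. At 30 µM labels it called 0 of 897 for PCSK9-B, PCSK9-C, PCSK9-D and Myd88-E (10, 48, 132 and 116 unadjusted; 0, 1, 7 and 0 with DESeq2). At 100 µM labels it called 0 of 903 for the same 4 (11, 8, 1 and 19 unadjusted; 0 with DESeq2). The median SE of a gene's log2 difference lay between 0.41 and 0.57 in these comparisons, so missing calls do not show that the ASOs act alike. The planned fit called 0 of 951 genes at 100 µM with edgeR (19, 12, 8 and 31 unadjusted; 0 with DESeq2).

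Whether the ASO response differed with EGF was tested by an interaction term. MYD88 in the planned fit at 100 µM gave interactions of 1.40 (SE 1.00) for Scramble-A, 1.25 (SE 1.00) for PCSK9-B, 2.39 (SE 1.05) for PCSK9-C, 0.63 (SE 1.11) for PCSK9-D and 2.34 (SE 1.01) for Myd88-E, none past the threshold (edgeR adjusted p from 0.506 to 0.994). No gene passed in any of the 15 comparisons within dose labels: edgeR called 0 of 916 genes at 10 µM labels (12 to 156 at an unadjusted p under 0.05), 0 of 928 at 30 µM labels (8 to 126) and 0 of 926 at 100 µM labels (33 to 129). DESeq2 called 1 gene, for PCSK9-C at 100 µM labels. On leaving out vehicle without EGF replicate 1, edgeR called 30 genes for Myd88-E and 1 for Scramble-A at 10 µM labels. The planned fit called 0 of 951 genes for each ASO with edgeR (152, 52, 42, 42 and 66 unadjusted; 0 with DESeq2). The median SE of an interaction within dose labels lay between 0.85 and 1.14.

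Dose dependence was fitted in the planned design as the ASO effect at 100 µM minus that at 10 µM, although the dose labels conflict. MYD88 with Myd88-E gave 1.96 (edgeR adjusted p = 0.0905). For Myd88-E 3 of 951 genes passed, which are named here after their values were seen: EPHA2, an ephrin receptor, at 2.69 (SE 0.67), LAMB1, a laminin chain, at 2.48 (SE 0.62), and DMBT1, a mucin-like scavenger receptor, at 6.27 (SE 1.57), each with an edgeR adjusted p = 0.0466. That count was 0 in edgeR with DESeq2 size factors, without the filter on low counts and with only the compared groups (290, 309 and 221 at an unadjusted p under 0.05), and 8 with DESeq2. It was 0 without vehicle replicate 2 or 3 or Myd88-E replicate 3, 152 without vehicle replicate 1 and 336 without Myd88-E replicate 1. For Scramble-A, PCSK9-B, PCSK9-C and PCSK9-D edgeR called 0 (139, 122, 100 and 98 at an unadjusted p under 0.05; 1, 0, 0 and 0 with DESeq2). Because no library is known to belong to 1 dose where it carries several, these values are not a dose response.

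Across the 951 genes of the planned fit, the fold changes of an ASO with and without EGF at 100 µM, which share no library, correlated at -0.09 for Scramble-A, 0.21 for PCSK9-B, 0.08 for PCSK9-C, 0.17 for PCSK9-D and 0.28 for Myd88-E. Genes are not independent replicates, so these are descriptions. Between ASOs the fold changes against the shared vehicle correlated at 0.66 to 0.80, where unchanged groups simulated against the same vehicle gave 0.42 to 0.51. The covariance was 0.339 to 0.534 against a simulated 0.173 to 0.183, a difference of 0.163 to 0.354 over 20 simulations per pair. Those simulations drew each gene on its own, without an EGF effect, so spread that genes share in the vehicle columns was left out. The excess therefore does not show a response common to the ASOs.

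A second way of handling the repeats kept each library once, where all its columns carried 1 label. For EGF this left 24 libraries with and 22 without. A single label need not be right, and the counts below rest on it. FGFR2 lay at 8.14 to 9.63 log2 CPM without and 5.41 to 7.77 with EGF at 10 µM labels. Labelled with EGF at 30 µM, it stood at 9.54 in a vehicle, 9.66 in a Scramble-A and 8.46 in a PCSK9-B library. Labelled without EGF at 30 µM, it stood at 5.29 in a PCSK9-D and 7.10 in a PCSK9-B library. All of these 30 µM libraries stood in a single column. STC1, stanniocalcin 1, rose by 2.29 (SE 0.38, edgeR adjusted p = 6.67e-05; 20 of 24 libraries), from 6.80 ± 1.38 log2 CPM (SD, n = 22) to 8.91 ± 1.76 (SD, n = 24). DUSP6 rose by 1.95 (SE 0.42), AREG by 1.52 (SE 0.37) and EGR1 by 1.60 (SE 0.45), and FGFR2 fell by 1.06 (SE 0.31). Of 837 genes 41 changed, 30 up and 11 down (edgeR; 191 at an unadjusted p under 0.05; 110 with DESeq2), and the 46 fits that left out 1 library gave 34 to 91 genes (62, 68 and 91 without EGF replicates 16 and 17 and no-EGF replicate 20), with 26 genes called in all of them. In the EGF and ERK response list 7 of 19 rose and 0 fell (11 adjusted over the list alone), with a median of 0.91 and a camera adjusted p = 2.56e-07, and adjusted p = 0.443 with an estimated correlation. The cell cycle median was 0.42 (0 of 19 past the test by edgeR, also adjusted over the list alone; camera adjusted p = 0.0401, and adjusted p = 0.655 with an estimated correlation). Removal of a GC trend gave 104 genes, 52 up and 52 down. The count was 24 with vehicle or ASO as a covariate in the 39 libraries with 1 such label, and 0 with the compound as a covariate in the 24 libraries with 1 compound label, so the libraries and the covariate changed together. It was also 0 among libraries standing in a single column, both zeros with edgeR (28 and 73 at an unadjusted p under 0.05). In the single-column libraries all 39 of these genes that were tested kept their direction, with a median ratio of 0.893 to the fold changes of all libraries. For ASOs, 34 libraries against 5 vehicle libraries gave 0 of 907 genes with edgeR (138 unadjusted; 18 with DESeq2), with a metallothionein median of 1.46 (4 of 5 higher adjusted over the list alone; camera adjusted p = 0.0110, and adjusted p = 0.630 with an estimated correlation), and their interaction with EGF 0 of 959 (9 unadjusted; 0 with DESeq2). Among single compounds 1 gene passed with edgeR, ITGA3, an integrin chain, which rose by 3.40 with PCSK9-D against vehicle (SE 0.71, edgeR adjusted p = 0.0361; 3 of 3 libraries), from 6.09 ± 0.28 log2 CPM (SD, n = 5) to 9.03 ± 1.44 (SD, n = 3). That count was 0 without any 1 of the 5 vehicle libraries or without PCSK9-D replicate 2, 3 without PCSK9-D replicate 3, and 19 with DESeq2 and 38 in edgeR with only the compared groups. For Scramble-A, PCSK9-B, PCSK9-C and Myd88-E against vehicle edgeR called 0 of 908 genes (6, 30, 120 and 169 unadjusted; 0, 0, 25 and 54 with DESeq2). Against Scramble-A it called 0 for PCSK9-B, PCSK9-C, PCSK9-D and Myd88-E (1, 134, 126 and 146 unadjusted; 0, 31, 16 and 53 with DESeq2).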

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

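All tests in this part were chosen after the results had been seen. Total counts, MYD88, EGF and EGFR were each checked for a column standing far from the others of its compound and dose label, in groups of 4 to 7 columns. Of these 72 checks 5 found one, where chance alone gives about 1 in 20. PCSK9-B at 10 µM without EGF replicate 1 had 8167100 total counts against 3128200 to 3941600 in the other columns of its compound and dose label. PCSK9-D at 100 µM without EGF replicate 1 had 8167100 against 2862200 to 3658300, and is the same library. PCSK9-C at 30 µM with EGF replicate 2 had 7307500 against 1964400 to 3881600. MYD88 stood at 4.55 log2 CPM in PCSK9-D at 100 µM with EGF replicate 1 against 7.24 to 7.71, and at 5.19 in Myd88-E at 100 µM without EGF replicate 1 against 7.48 to 8.2. Both MYD88 values came from libraries without a conflicting compound label.

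The first pattern weighed is that the same counts stand under different labels. Independent libraries agreeing by chance is argued against, because the 2 most similar distinct libraries differed in 912 genes. A candidate explanation is that columns were filled in title order from fewer count columns: of the library pairs shared by 2 dose labels, 100% stood in the same title order in both, where 2000 shuffles reached at most 63.75%. EGF labels accounted for 15.8% of the variance between columns at 10 µM labels (permutation p = 2e-05), 2.38% at 30 µM labels (p = 0.497) and 14.6% at 100 µM labels (p = 0.00035), and compound labels for 20.0% (p = 0.0123), 16.8% (p = 0.181) and 14.3% (p = 0.397), 6 permutation tests without adjustment. This may mean that EGF and compound labels hold in part of the 10 µM columns and EGF labels in part of the 100 µM columns, whereas whether any label holds elsewhere cannot be told apart from a mislabelled set, since the tests could miss a small share of right labels.

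The second pattern is that EGF genes were called at 10 and 100 µM labels and none at 30 µM. A transcript GC trend and sequencing depth are argued against as whole causes of the calls: of the 322 calls at 10 µM labels 315 remained after removal of the GC trend and 304 after thinning to 1 total, and of the 271 calls at 100 µM labels 222 and 234 remained. That libraries with both EGF labels hide part of the response at 30 µM goes with the values below. It stays open how large a part, because 10 of them entered the 10 µM fit, which chose the genes, under the other EGF label. Over the genes called at 10 µM the median ratio of the log2 fold change at 30 µM to that at 10 µM was -0.177. It was 0.198 without those libraries, against 0.682 for 100 µM. For FGFR2, libraries with 1 EGF label argue against them as the whole cause. At 10 µM labels it lay at 8.14 to 9.63 log2 CPM without and 5.41 to 7.77 with EGF. Labelled with EGF at 30 µM, it stood at 9.54 in a vehicle, 9.66 in a Scramble-A, and 8.46 and 9.76 in PCSK9-B libraries. Labelled without EGF, it stood at 5.29 in a PCSK9-D and 7.10 in a PCSK9-B library. The other libraries with 1 EGF label stood on their label's side. Libraries with both EGF labels stood opposite their 30 µM label for FGFR2. They lay at 8.14 to 9.46 where labelled with EGF and at 6.64 to 7.66 where labelled without. A biological cause in the ASO concentration was not tested, since the dose labels conflict.

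The third pattern is the large spread between libraries, whose first and second components held 33.1% and 22.6% of the variance. A cubic trend over transcript GC accounted for 16.5% of the variance between libraries, where 1000 shuffles of GC reached at most 2.76%. The first component correlated with log2 total counts over the 57 libraries (Pearson r = 0.628, Spearman rho = 0.593, both permutation p = 1e-05, the smallest these permutations can give; r = 0.595 without the 2 libraries farthest from the median). Depth and GC could therefore contribute, but neither can be told apart from treatments that change the same genes. No biological explanation was tested.

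Other splits of the columns into arms of the same sizes were refitted for the comparisons with at least 3 columns or libraries per arm, which left out PCSK9-C (2 libraries) and the interaction with EGF (1 vehicle library with EGF) over libraries with 1 label. For EGF at 10 µM labels 1 of 100 splits, the real one, gave as many as 322 genes, with 112 the highest of the others. At 100 µM labels 1 of 100 gave as many as 271, with 170 the highest other. No other drawn split reached either count, and 1 of 100 is the smallest share these splits can give. Fewer than 0.05 of the splits also gave as many genes for Myd88-E against vehicle at 10 µM labels (117 genes, 2 of 100 splits, highest other 284). The same held for PCSK9-C against Scramble-A at 10 µM labels (2 genes, 4 of 100, 87). It held for EGF over libraries with 1 EGF label (41 genes, 4 of 100, 153) and PCSK9-D against vehicle over libraries with 1 label (1 gene, 4 of 100, 134). In the planned fit it held for the difference of Myd88-E between 100 and 10 µM (3 genes, 1 of 40, 0). The splits of that fit moved repeated libraries as separate columns. No adjustment was made over these comparisons, and among so many refits some fall under 0.05 without any effect. Chance is therefore not excluded by the splits alone for any of these results. For EGF the separate permutation of labels, also unadjusted, gave p = 2e-05 at 10 µM labels and p = 0.00035 at 100 µM labels. Why some splits called several times the real count was not tested. Chance is likewise not excluded for PCSK9-C against vehicle at 10 µM labels (21 genes, 5 of 100, 200). Nor is it in the planned fit for PCSK9-D (8 genes, 2 of 40, 43) and Myd88-E (12 genes, 2 of 40, 85) at 30 µM. For the 74 refitted comparisons with 0 genes by edgeR, 100 of 100 or 40 of 40 splits gave as many. A real count of 0 fixes that share in advance, so it tests nothing. In 58 of those comparisons a split called more, up to 345.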

How the results depend on the processing

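Fits of libraries with 1 label, fits within dose labels, covariates, subsets of libraries, thinning and GC correction were chosen after the data had been seen, and the other alternatives were planned. Counts are genes past the threshold by edgeR unless DESeq2 is named. No paired analysis was made, because the titles carry no replicate numbers that link groups. The titles are numbered in order, and a block by title order was not fitted. Most original counts were 0, which counts as kept where the alternative is 0 too. At 30 µM labels all originals were 0, and at 100 µM labels all but EGF. On this measure, within dose labels 81 of the alternative counts at 10 µM, 100 at 30 µM and 101 at 100 µM lay within 1.5 times their original, as did 157 of the planned fit and 58 over libraries with 1 label. For the others the cause was not tested, except that fits of fewer columns have less power.

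Over libraries with 1 label, the 41 EGF genes became 63 without the count filter, 110 with DESeq2, 104 with the GC trend removed, 24 with vehicle or ASO as covariate (in the 39 libraries with 1 such label), 0 with compound as covariate (in the 24 libraries with 1 compound label), 0 in libraries of a single column, 27 in libraries of several columns and 12 in ASO libraries only. ASO against vehicle (0) became 2 without the count filter and 18 with DESeq2. With DESeq2 the compound counts against vehicle were 25 for PCSK9-C, 19 for PCSK9-D and 54 for Myd88-E, and against Scramble-A 31, 16 and 53. With only the groups compared they were 1 for PCSK9-C and 38 for PCSK9-D against vehicle, and 11 for PCSK9-D and 4 for Myd88-E against Scramble-A. PCSK9-C against Scramble-A gave 1 with the GC trend removed. The 1 gene of PCSK9-D against vehicle became 10 in cultures without EGF only and 0 in cultures with EGF only.

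In the planned fit, the 12 genes of Myd88-E at 30 µM became 0 with DESeq2 size factors, 0 without the count filter, 128 with DESeq2, 0 with vehicles pooled, 106 with only the groups compared, 0 without EGF and 2 with EGF. The 8 genes of PCSK9-D at 30 µM became 5 without the count filter, 22 with DESeq2, and 0 with only the groups compared, without EGF or with EGF. DESeq2 gave 6 for PCSK9-C at 10 µM, 18 for Myd88-E at 10 µM and 3 for Myd88-E at 100 µM, and PCSK9-C at 10 µM gave 33 with vehicles pooled. The 3 genes of Myd88-E between 100 and 10 µM became 0 with DESeq2 size factors, without the count filter and with only the groups compared, and 8 with DESeq2, which gave 1 for Scramble-A. EGF gave 303 averaged over all 6 treatments, which counts repeated libraries several times.

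At 10 µM labels, the 21 genes of PCSK9-C against vehicle became 7 without the count filter, 76 with the GC trend removed, 69 with DESeq2, 12 thinned, and 0 with only the groups compared or in each EGF state. The 117 of Myd88-E became 2, 232, 272, 196, 0 and 0 in the same order. PCSK9-B against vehicle gave 1 with the GC trend removed. PCSK9-B against Scramble-A gave 44 with DESeq2, 30 thinned and 27 with only the groups compared, and the 2 genes of PCSK9-C against Scramble-A became 1 thinned, 1 with only the groups compared and 0 in each EGF state. EGF gave 4 in vehicle cultures only and 186 without libraries of both EGF labels. At 30 µM labels DESeq2 gave 1 for EGF, 6 for Myd88-E against vehicle, and 1 and 7 for PCSK9-C and PCSK9-D against Scramble-A, and Myd88-E gave 89 with only the groups compared. At 100 µM labels DESeq2 gave 7 for Myd88-E against vehicle and 1 for the PCSK9-C interaction, and EGF gave 0 in vehicle cultures only and 95 without libraries of both EGF labels.

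Of the named gene values, 1932 kept their side of the threshold, 501 lost it and 2 gained it. The 1932 can hold changes of sign in genes called in neither fit. Another 12 that were called in the original fit reversed, all for EGF in vehicle cultures only and none past the threshold there. At 10 µM labels these were VDR -0.19, HERPUD1 0.034, MT1E -0.45 and MT1X -1.0, and at 100 µM labels EMX2 0.90, DUSP1 -0.19, TP53I3 0.20, BCL2L11 0.25, SLC2A1 0.59, KRT19 0.15, ZBTB16 0.93 and KLF9 0.67.

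Leaving out 1 replicate, 60 of 87 results stayed at 0. Over libraries with 1 label EGF gave 34 to 91 (lowest without EGF replicate 22, highest without no-EGF replicate 20), PCSK9-D against vehicle 0 to 3, Myd88-E against vehicle 0 to 21 (without Myd88-E replicate 4) and PCSK9-D against Scramble-A 0 to 3 (without PCSK9-D replicate 3). In the planned fit the ranges were 0 to 1 for PCSK9-C and 0 to 71 for Myd88-E (without its replicate 2) at 10 µM, 0 to 23 for PCSK9-D and 0 to 127 for Myd88-E at 30 µM, and 0 to 197 for Myd88-E (without its replicate 1) at 100 µM; between 100 and 10 µM they were 0 to 1 for Scramble-A and PCSK9-C (without vehicle replicate 1), 0 to 2 for PCSK9-B (without vehicle replicate 2) and 0 to 336 for Myd88-E (without its replicate 1). At 10 µM labels they were 278 to 354 for EGF, and against vehicle 0 to 4 for Scramble-A, 0 to 221 for PCSK9-B, 1 to 198 for PCSK9-C, 0 to 44 for PCSK9-D and 0 to 294 for Myd88-E, where the highest of the first 4 came without vehicle without EGF replicate 2. Against Scramble-A they were 0 to 41 for PCSK9-B (without Scramble-A without EGF replicate 3), 1 to 2 for PCSK9-C and 0 to 1 for Myd88-E, and the interactions gave 0 to 1 for Scramble-A and 0 to 30 for Myd88-E (without vehicle without EGF replicate 1). At 30 µM labels EGF gave 0 to 1. At 100 µM labels EGF gave 227 to 340 and Myd88-E against vehicle 0 to 124 (without Myd88-E without EGF replicate 1). Depth was at least 1658672 counts per library, and thinning to 1 total kept 304 of 322 and 234 of 271 EGF calls at 10 and 100 µM labels.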

Other observations

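The fits within dose labels, and so all tests in this part, were chosen after results had been seen. Several other groups held genes that changed with EGF at 10 µM labels without a list-wide call by limma camera. In the apoptosis machinery 6 of 20 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.648): BCL2L1, an inhibitor of apoptosis, rose by 1.09, and BCL2L11, its pro-apoptotic relative, fell by 0.97. In TGF-beta and matrix genes 4 of 20 rose and 2 fell (the same adjusted over the list alone; camera adjusted p = 0.648), with CTGF, a matrix-associated growth factor, up by 1.19. Proximal tubule function genes had 3 of 9 up and 2 down (the same adjusted over the list alone; camera adjusted p = 0.649): CYP24A1, the vitamin D 24-hydroxylase, rose by 2.47 (SE 0.37; 18 of 18 columns), and SLC47A1, an organic cation exporter, fell by 1.25. Glucocorticoid response genes had 2 of 10 up and 2 down (the same adjusted over the list alone; camera adjusted p = 0.666), with ZBTB16 down by 1.81. Hypoxia and glycolysis genes had 2 of 11 up and 1 down (the same adjusted over the list alone; camera adjusted p = 0.874), HK2, a hexokinase, rising by 1.03 and ADM, adrenomedullin, falling by 1.01. Metallothioneins had 2 of 5 up, MT1E by 0.93 and MT1X by 0.94 (2 adjusted over the list alone, camera adjusted p = 0.510). In vehicle columns alone they differed by -0.45 and -1.0, neither past the threshold (edgeR adjusted p = 0.809 and 0.560). Toll-like receptor genes had 1 of 7 up and 2 down (the same adjusted over the list alone; camera adjusted p = 0.874), TLR4 rising by 1.06 and TLR5 falling by 0.94, while MYD88 differed by -0.11 (SE 0.22, edgeR adjusted p = 0.724). P53 and DNA damage genes had 1 of 14 up and 3 down (camera adjusted p = 0.988), unfolded protein response genes 1 of 9 up and 2 down (0.970) and NRF2 genes 2 of 11 up and 3 down (0.897), with the same counts adjusted over the list alone, and lysosome genes 1 of 11 up and 1 down (0.874; 0 up and 1 down adjusted over the list alone). Heat shock genes (0 of 6) and kidney injury markers (0 of 9) had no call by edgeR, also adjusted over the list alone (camera adjusted p = 0.649 and 0.988).

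At 100 µM labels hypoxia and glycolysis genes had 1 of 10 up and 4 down (2 and 5 adjusted over the list alone; camera adjusted p = 0.733), with ADM down by 1.59. P53 and DNA damage genes had 2 of 15 up and 4 down (camera adjusted p = 0.876), glucocorticoid response genes 3 of 10 up and 2 down (0.733; 3 and 3 adjusted over the list alone), TGF-beta and matrix genes 2 of 20 up and 4 down (0.976) and kidney injury markers 1 of 9 up and 2 down (0.919), the counts of the other 3 lists being the same adjusted over the list alone. SOD1, a cytosolic superoxide dismutase, and GSTP1, a glutathione transferase, fell by 1.28 and 1.15. Outside the rule for naming genes and chosen after their values were seen, STC1, a secreted glycoprotein hormone, rose by 2.78 (SE 0.19, edgeR adjusted p = 5.50e-15; 18 of 18 columns) at 10 µM labels and by 2.24 (SE 0.37; 14 of 16) at 100 µM labels. DKK1, a secreted WNT inhibitor, rose by 2.36 (SE 0.25) and 2.21 (SE 0.35), and ABCA1, the cholesterol efflux transporter, fell by 1.96 (SE 0.30) and 2.14 (SE 0.43). At 30 µM labels STC1 differed by -0.46 (SE 0.53), DKK1 by -0.82 (SE 0.48) and ABCA1 by 0.04 (SE 0.39), none past the threshold.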
